A study of Homo sapiens with 6 samples.

How the data were processed

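The values were taken as deposited: TPM, made by the authors, with 59050 entries named by gene symbol in 6 libraries, each library summing to between 998367 and 998843. Per the submitters' processing notes, Trim Galore 0.6.6, STAR and StringTie were used, with GRCh38. The gene annotation and the strand setting are not given in the sources used here, and no scaling between libraries is recorded. The column of DMSO replicate 3 also holds TPM as deposited by the authors, but 1 value in it (MTND5P11) lay slightly below 0 and was set to 0. Read depth is unknown for TPM, so no detection limit was computed. Per the labels, cells at about passage 18 were selected with 200 µg/ml neomycin, and the libraries were made from 1 µg of total RNA.

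Of the symbols, 27 had been turned into dates and 2 stood on 2 entries each. Positions come from GENCODE 29, in which 56132 of the symbols were unique. Of 677 listed genes 674 were matched, 26 of them by an older symbol, and KIF23, OAS1 and MCAM are not analysed here.

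Genes with a mean of at least 1 TPM over the 6 libraries were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend) on log2(TPM + 1), 2-sided, without covariates. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The choices of the test, the gene lists, the named genes and most alternative settings were made before the data were examined. Lists with at least 5 tested members were compared with all other genes by limma's camera (preset correlation 0.01, 2-sided, Benjamini-Hochberg over the 30 lists), and again with a correlation estimated from the data. They were also tested by fry, which asks only whether members move on balance in a direction and compares them with no other genes. The list p-values in the text are those adjusted values. As alternatives, TPM were scaled between libraries by the median of ratios to the geometric mean of each gene, or by quantile normalization, and the filter, pseudocount, variance trend and set of libraries were changed in turn. Shares of the libraries were compared by an exact permutation test, 2-sided.

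Named genes were chosen by a rule of 3 parts. The first is 23 core genes. The second is the 10 largest increases and the 10 largest decreases among genes past the threshold with a mean of at least 5 TPM, groups that do not overlap and a symbol that is not a clone name, pseudogene or unnamed locus. The third is the 2 members of each list with the largest change among those past the threshold. This gave 95 genes, some of which are not reported here, and any other gene is said to have been chosen after its values were seen.

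The 34 lists cover the cell cycle, DNA replication, DNA repair, lamina and senescence-linked chromatin, cyclin-dependent kinase inhibitors and damage response, RAS/MAPK response, secreted cytokines, secreted proteases, secreted growth factors, NF-kB targets, interferon response, TGF-beta and myofibroblast genes, collagen and matrix, Notch, NRF2, autophagy, lysosome, unfolded protein response, cholesterol synthesis, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, ribosome biogenesis, nucleoporins, histones and oestrogen receptor targets. The others are markers of fibroblasts, smooth muscle cells and pericytes, keratinocytes and epithelia, endothelium, immune cells, melanocytes and HEK293 cells, in which the viral vector was packaged.

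The comparison was tested on simulated data of 3 against 3 libraries, with the spread of the deposited values. The 200 changed genes were drawn from the 15272 tested in the real data, and 15010 genes were tested in the simulated data. The comparison recovered 47% of changes of 0.5 log2 units, 79.1% of changes of 1 and 91% of changes of 2. Changed genes that the filter removed count as missed in these shares. Of its 151 calls 6 (3.97%) were false. These rates need not hold for the real comparison, in which 49.6% of the tested genes were called. The simulated noise was independent between genes, and no shift between libraries was simulated. Replicates were close: the median coefficient of variation over 11055 genes of at least 5 TPM was 6.76% in 4-OHT and 6.53% in DMSO. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9 and blastn 2.17.0 were used for tables, plots and sequence identity.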

Results

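Bulk RNA-seq was collected from human foreskin fibroblasts (HFF) that carried ER:RAS, a fusion of oncogenic H-RAS with the hormone-binding domain of the oestrogen receptor that 4-hydroxytamoxifen (4-OHT) switches on at the protein level. Cells received 100 nM 4-OHT or its vehicle DMSO and were harvested after a week, with 3 libraries per group. Levels below are TPM, given as mean ± SD of the 3 libraries of a group, 4-OHT first. Log2 fold changes are 4-OHT minus DMSO on the log2(TPM + 1) scale, which understates the change of genes at low levels.

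In the 4-OHT libraries the genes of cell division and DNA replication fell together, and LMNB1 and HMGB2, whose loss is known from senescent cells, fell with them. The cyclin-dependent kinase inhibitors CDKN2B, CDKN1A and CDKN2A rose, CDKN2B by 24.3-fold, while CDKN1C, at a low level in both groups, fell. Genes of the RAS/MAPK response, secreted proteases and a set of secreted cytokines that includes IL1A, IL1B and CXCL8 rose as well. The chemokines CXCL12 and CCL2 and the keratin KRT19 were among the genes that fell most.

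The HRAS transcript itself stood at 1281 ± 51.1 against 936 ± 24.7 TPM (log2 fold change 0.45, SE 0.0403, adjusted p = 9.99e-05) and ranked 118th of all genes by mean level. The row for HRAS (chromosome 11, 532242 to 537287, GRCh38) takes up reads of the introduced and of the cells' own transcript without separating them. ESR1, whose hormone-binding domain is part of the fusion, stood at 72.4 ± 1.61 against 47.5 ± 1.76 (log2 fold change 0.60, chosen after its values were seen). NRAS was at 65.5 ± 3.28 against 59.9 ± 1.98 (0.13, adjusted p = 0.103), which passed the test only under median-of-ratios scaling (0.25, adjusted p = 0.0072; 0.0072 to 0.27 over the alternatives).

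Of 15272 genes tested, 3018 were higher and 4561 lower in 4-OHT (49.6% of those tested). Of these, 644 were higher and 1254 lower by at least 1 log2 unit. In 9005 genes (59.0%) the 3 libraries of a group lay entirely above those of the other, where 10% would do so by chance. This held for 7529 of the genes called. The first principal component, which separated the groups, held 75.5% of the variance and the second 6.78%. The balance of directions depended on the scaling. As deposited, 60.2% of the called genes were lower, against 47% under median-of-ratios scaling (4040 higher and 3579 lower) and 49.7% under quantile normalization (3650 higher and 3604 lower). Under median-of-ratios scaling the log2 fold changes of the genes shifted upward by a median of 0.113. The p-values measure only the spread between these samples, since nothing in the labels says whether the replicates came from separate cultures.

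**Figure D1:**
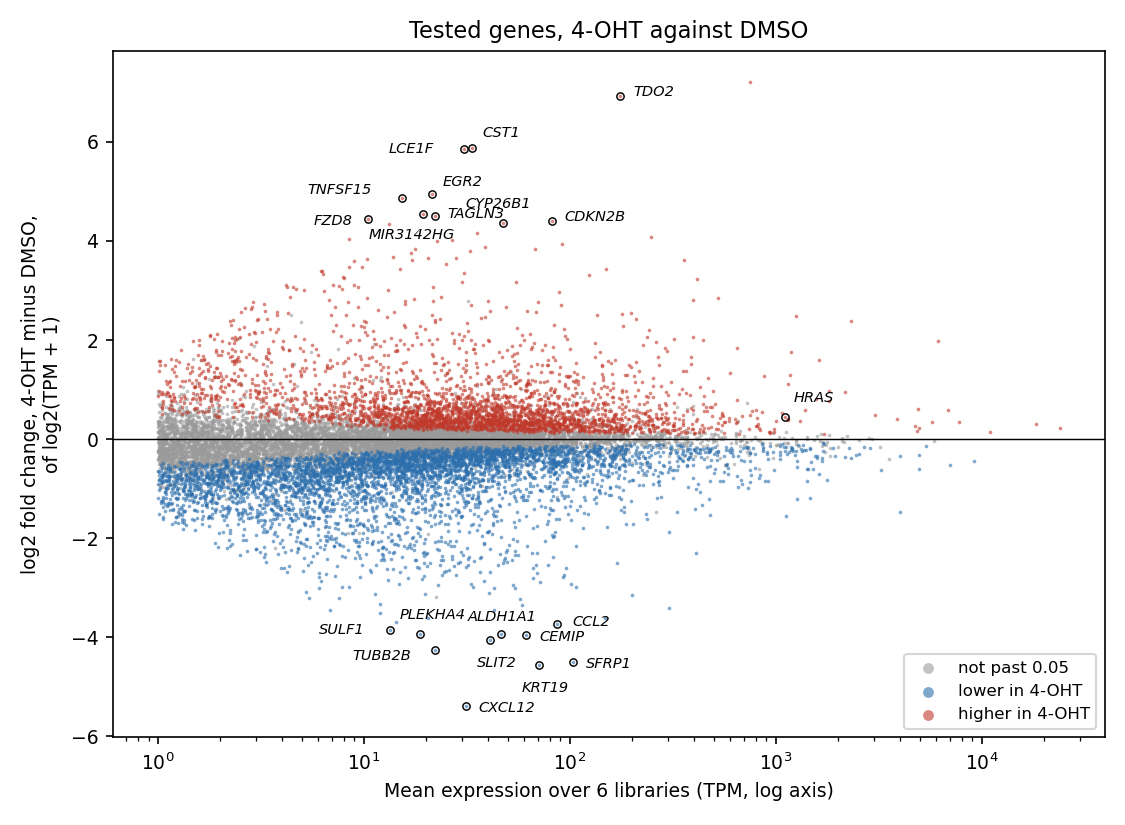
Log2 fold change (4-OHT minus DMSO, of log2(TPM + 1)) of each tested gene against its mean over the 6 libraries (TPM, log axis), coloured by call (adjusted p under 0.05), with the genes of largest change named by the rule and HRAS circled; genes specific to the sex chromosomes were left out of the plot. TDO2 (6.92) and CXCL12 (-5.39) lie at the far ends of the named genes.

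Every gene named below as having risen or fallen had its 3 4-OHT libraries entirely above or entirely below its 3 DMSO libraries. The largest increase among the genes named by the rule was that of TDO2 (chromosome 4, 155854738 to 155920406), an enzyme that starts the breakdown of tryptophan, at 351 ± 7.89 against 1.91 ± 0.209 TPM (6.92, adjusted p = 1.85e-08). CST1, a secreted inhibitor of cysteine proteases, was read at 63.3, 66.9 and 70.5 in 4-OHT and at 0.18, 0 and 0.297 in DMSO (5.88). LCE1F, of the late cornified envelope family, was read at 65.3, 58.3 and 60.0 in 4-OHT, and in DMSO at 0.244 in 1 library and listed at 0 in the others (5.85). The transcription factor EGR2 rose from 0.425 ± 0.241 to 42.6 ± 1.6 (4.95, adjusted p = 5.6e-07) and the cytokine TNFSF15 from 0.0845 ± 0.0603 to 30.4 ± 1.88 (4.86). MIR3142HG, a long non-coding RNA, was at 41.9, 37.6 and 33.5 in 4-OHT and at 0, 0.0149 and 3.36 in DMSO (4.55, adjusted p = 0.000431). The Wnt receptor FZD8 was at 20.3, 20.5 and 21.8 in 4-OHT and listed at 0 in all 3 DMSO libraries (adjusted p = 3e-07). TAGLN3 (43.5 ± 4.14 against 0.983 ± 0.344, log2 fold change 4.50) and CYP26B1, an enzyme that degrades retinoic acid (91.3 ± 0.285 against 3.71 ± 1.9, log2 fold change 4.36), completed the rule's genes with CDKN2B.

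The largest decrease was that of CXCL12 (chromosome 10, 44370165 to 44386493), a chemokine, at 0.524 ± 0.319 against 62.0 ± 2.06 TPM (-5.39, adjusted p = 5.57e-07), 118-fold lower. KRT19 was 28.2-fold lower (4.84 ± 0.229 against 136 ± 7.09). SFRP1, a secreted antagonist of Wnt ligands, fell from 199 ± 3.2 to 7.90 ± 1.06 (-4.50). The tubulin TUBB2B (1.44 ± 0.929 against 43.0 ± 2.15), the guidance ligand SLIT2 (3.74 ± 0.164 against 77.9 ± 4.7) and the hyaluronan-binding protein CEMIP (6.62 ± 0.0193 against 117 ± 6.94) fell. ALDH1A1, a retinaldehyde dehydrogenase, fell from 87.7 ± 2.94 to 4.81 ± 0.206, PLEKHA4 from 36.1 ± 1.13 to 1.45 ± 0.411, and the extracellular sulfatase SULF1 from 25.9 ± 0.887 to 0.942 ± 0.749. CCL2, which attracts monocytes, was at 11.4 ± 0.724 against 163 ± 8.53 (-3.73), 14.3-fold lower.

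Lists of genes fixed beforehand were then tested against all other genes. Of 30 lists with at least 5 tested members, 10 were higher, 7 lower and 13 not called, and 9 of these calls held with an estimated correlation (adjusted p from 0.012 to 0.045). Adjusted over the list alone, the numbers of members that rose and fell were the same as over all genes tested in every list but those of Notch, nucleoporins and lysosome, where they are given beside the others.

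All 27 tested genes of the cell cycle fell (median -2.39, adjusted p = 5.1e-17 for the list), and so did all 26 of DNA replication (median -2.03, adjusted p = 3.8e-15). The proliferation marker MKI67 stood at 5.17 ± 0.38 against 34.1 ± 1.29 TPM (-2.51) and the cyclin CCNA2 at 9.26 ± 1.48 against 64.1 ± 3.54 (adjusted p = 2.99e-06). The mitotic kinesin KIF20A was at 7.64 ± 0.518 against 73.1 ± 1.97 (-3.10) and BIRC5 at 15.7 ± 0.286 against 117 ± 3 (-2.81). TK1 (22.8 ± 1.81 against 179 ± 9.44) and TYMS (50.5 ± 2.89 against 290 ± 7), which make thymidine nucleotides, fell by 2.92 and 2.50 log2 units. Of 20 genes of DNA repair, 18 fell and 1 rose (median -1.64, adjusted p = 1.4e-06). All 15 genes of the nuclear lamina and senescence-linked chromatin proteins fell (median -1.76, adjusted p = 1.4e-08). LMNB1 (chromosome 5) was at 6.87 ± 1.1 against 61.1 ± 5.5 (-2.99, adjusted p = 2.3e-06), 8.89-fold lower. HMGB2 was at 22.0 ± 6.19 against 273 ± 15.5 (adjusted p = 7.41e-06), 12.4-fold lower. Among 19 nucleoporins 14 fell and none rose (16 fell adjusted over the list alone; under median-of-ratios scaling 11 fell and 2 rose). Their median was -0.41 (adjusted p = 0.0015, or adjusted p = 0.19 with an estimated correlation). NUP107 (11.4 ± 0.284 against 26.8 ± 2.77) and NUP37 (20.1 ± 1.34 against 45 ± 4.55) fell most.

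Of 27 genes of the cyclin-dependent kinase inhibitors and damage response, 16 rose and 6 fell (median 0.27, adjusted p = 2e-04). CDKN2B (chromosome 9, 22002903 to 22009363), which encodes p15, was at 158 ± 3.97 against 6.47 ± 0.129 (4.41, adjusted p = 2.8e-08). CDKN1A, which encodes p21, was at 1659 ± 57.1 against 679 ± 15.7 (1.29, adjusted p = 5.6e-07), and CDKN2A, which encodes p16 and ARF, at 41.5 ± 4.68 against 20.4 ± 2.09 (0.99, adjusted p = 0.000247). The symbol rows do not part the p16 and ARF transcripts. CDKN1C, which encodes p57 and was chosen after its values were seen, was at 0.515 ± 0.171 against 2.70 ± 1.57 (-1.19, adjusted p = 0.0228). Its call was not followed through the alternative settings. RRM2B, a damage-induced subunit of ribonucleotide reductase, rose (104 ± 5.53 against 40.2 ± 3.4). The stress-responsive cytokine GDF15 was at 163 ± 30.5 against 67.7 ± 6.91 (1.24, adjusted p = 0.000355). GLB1, which encodes the lysosomal beta-galactosidase, was at 93.9 ± 1.36 against 87.6 ± 9.55 (0.11, adjusted p = 0.301) and passed the test under median-of-ratios scaling (0.22, adjusted p = 0.048) and without DMSO replicate 3 (0.19, adjusted p = 0.039; 0.039 to 0.71 over the alternatives).

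**Figure D2:**
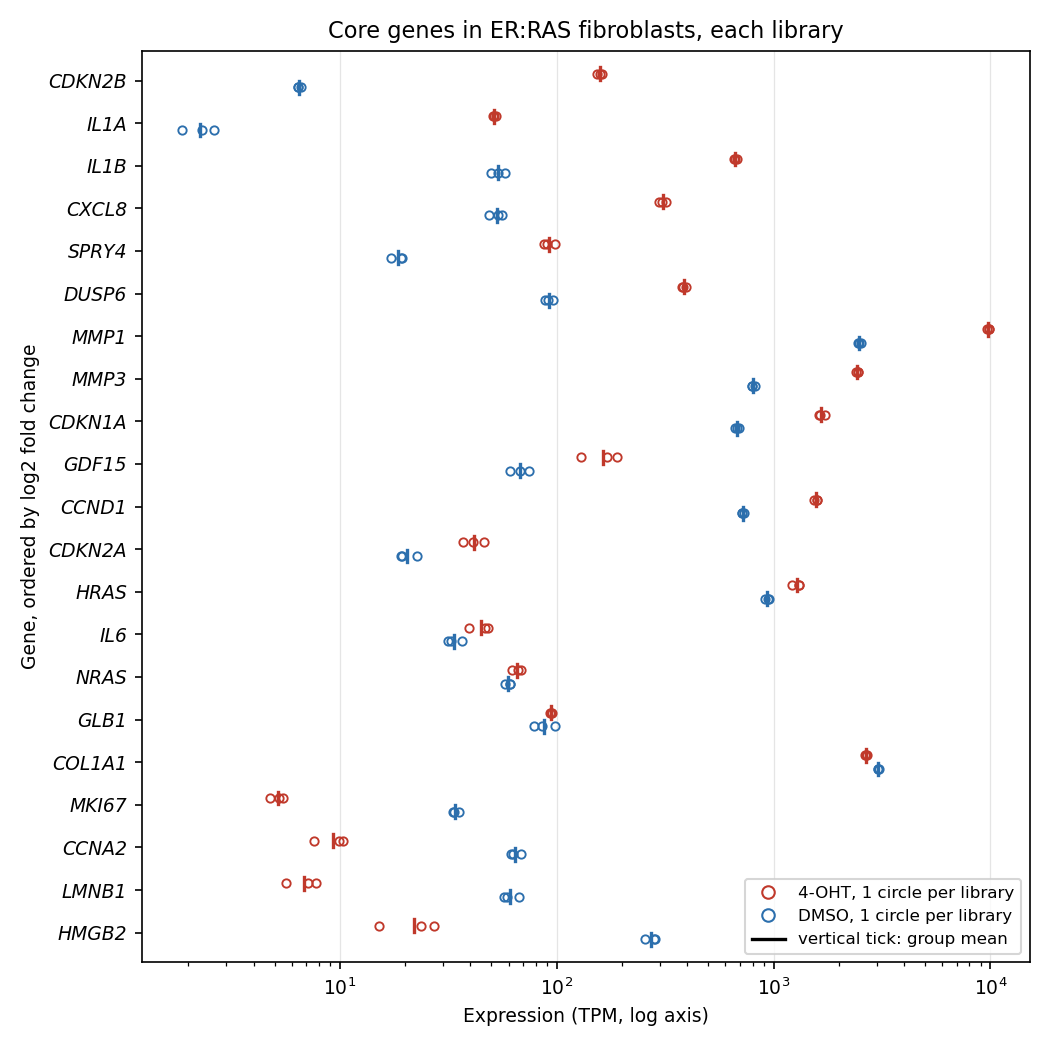
TPM (log axis) of 21 core genes in each library, with a circle per library and a tick at the mean of each group. MMP1 is the highest of them, at 9774 TPM in 4-OHT, and LMNB1, HMGB2, MKI67 and CCNA2 lie lower in 4-OHT than in DMSO.

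In the list of RAS/MAPK response genes 21 of 25 rose and 2 fell (median 1.25, adjusted p = 6.8e-12). DUSP6, a phosphatase of ERK, rose from 91.9 ± 3.89 to 385 ± 7.41 TPM (2.05, adjusted p = 1.9e-07) and SPRY4, a feedback inhibitor, from 18.6 ± 1.22 to 92.1 ± 5.81 (2.25). IER3 was 7.25-fold higher, at 923 ± 24.2 against 127 ± 3.77, and the cyclin CCND1 was at 1569 ± 30 against 721 ± 9.19 (1.12, adjusted p = 4.45e-07).

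Secreted cytokines of the senescence-associated secretory phenotype rose in 13 of 24 genes and fell in 5 (median 0.39, adjusted p = 0.00048). IL1A was at 51.6 ± 0.8 against 2.27 ± 0.382 (4.01, adjusted p = 3.53e-07), IL1B at 665 ± 10.7 against 53.7 ± 4.1 (3.61, adjusted p = 7.48e-08) and CXCL8 at 308 ± 12.8 against 52.8 ± 3.81 (2.52, adjusted p = 3.17e-07). CSF2, a growth factor of granulocytes and macrophages, was at 43.5 ± 0.319 against 1.83 ± 0.504 (adjusted p = 1.23e-06). IL6 rose far less, at 44.9 ± 4.63 against 33.6 ± 2.55 (adjusted p = 0.00952). The 5 members that fell include CCL2 (-3.73) and CSF1, the latter chosen after its values were seen and given further below. Secreted proteases and their regulators rose in 16 of 20 genes and fell in 2 (median 1.39, adjusted p = 2.1e-09). The collagenase MMP1 stood at 9774 ± 126 against 2482 ± 35.8 TPM (1.98, adjusted p = 3.97e-08) and the stromelysin MMP3 at 2425 ± 26.8 against 804 ± 15.7 (1.59). SERPINB2 (470.2 ± 15.1 against 28 ± 9.28, log2 fold change 4.08) and STC1 (699 ± 11.7 against 98.4 ± 2.21, log2 fold change 2.82) rose most in that list. Secreted growth factors were not called as a list (9 rose and 7 fell of 19, median 0.07, adjusted p = 0.3), though ANGPTL4 (15.3 ± 2.3 against 0.729 ± 0.373) and the epidermal growth factor receptor ligand EREG (352 ± 9.38 against 64.8 ± 3.66) rose.

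Targets of NF-kB were not called (9 rose and 5 fell of 17, adjusted p = 0.17), with a median of 0.13, a mean of -0.02 and a test direction of higher. PTGS2, the inducible cyclooxygenase, fell from 17.5 ± 2.56 to 5.30 ± 0.565 (-1.55). Complement factor CFB was at 0.482 ± 0.173 against 2.51 ± 1.3 (adjusted p = 0.019). That call was lost without 4-OHT replicate 1 and without DMSO replicate 1 or 2 (adjusted p = 0.058, 0.065 and 0.066) and with no filter on low values (0.091), the highest over the alternatives, where the lowest was 0.0019. Interferon-stimulated genes were not called either (4 rose and 7 fell of 19, adjusted p = 0.83), and their median of -0.07 changed sign under median-of-ratios scaling (0.05) and quantile normalization (0.10). IFIT1 (3.87 ± 0.284 against 22.7 ± 0.963) and IFIT2 (2.47 ± 0.133 against 9.52 ± 0.524) fell most among them.

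In the list of TGF-beta response and myofibroblast genes 9 of 17 rose and 6 fell (median 0.52, adjusted p = 0.036, or adjusted p = 0.18 with an estimated correlation). The call was also lost under quantile normalization (0.082), among genes of at least 5 TPM (0.077), among protein-coding genes only (0.056) and without DMSO replicate 2 (0.052). The protein-coding setting was chosen after the data were seen. PMEPA1 rose from 2.13 ± 0.177 to 24.1 ± 0.523 (3.01) and the contractile protein CNN1 fell from 36.1 ± 2.47 to 5.57 ± 0.228 (-2.50). Of 14 Notch pathway genes 7 rose and 2 fell (8 and 2 adjusted over the list alone). Their median was 0.61 (adjusted p = 0.0093, or adjusted p = 0.1 with an estimated correlation). The Notch target HEYL was at 14.6 ± 0.874 against 1.76 ± 0.183 (2.50) and LFNG, which glycosylates Notch, at 22.6 ± 0.55 against 3.30 ± 0.652 (2.47). Collagen and matrix genes went both ways (9 rose and 11 fell of 24, 11 and 9 under median-of-ratios scaling, adjusted p = 0.99), with a median of -0.06 that turned to 0.06 under median-of-ratios scaling, a mean of -0.02 and a test direction of higher. In that list VCAN (24.4 ± 2.55 against 7.55 ± 0.478) and ELN (2.78 ± 0.262 against 0.405 ± 0.0878) rose. COL1A1 was at 2671 ± 34.2 against 3044 ± 26.6 (-0.19, adjusted p = 0.000998) and did not pass the test under median-of-ratios scaling (-0.07, adjusted p = 0.073; 0.00049 to 0.073 over the alternatives).

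Of 22 genes of cholesterol synthesis 15 fell and none rose (median -0.52, adjusted p = 0.00012). HMGCS1, an early enzyme of the pathway, fell from 90.5 ± 6.52 to 31.5 ± 11.6 (-1.55). Autophagy genes rose in 9 of 21 with none lower (median 0.23, adjusted p = 0.001, or adjusted p = 0.053 with an estimated correlation). MAP1LC3B (270 ± 5.82 against 147 ± 4.82) and WIPI1 (180 ± 6.14 against 109 ± 6.93), both of the autophagosome, rose most. Targets of NRF2 and antioxidant genes rose in 11 of 20 and fell in 6 (median 0.36, adjusted p = 0.011, or adjusted p = 0.11 with an estimated correlation and 0.061 under quantile normalization). TXNRD1 was higher (378 ± 9.16 against 179 ± 3.92) and AKR1C1 lower (1.64 ± 0.317 against 4.65 ± 0.738). Nuclear genes of oxidative phosphorylation rose in 10 of 24 with none lower (median 0.11, adjusted p = 0.0015, or adjusted p = 0.1 with an estimated correlation and 0.065 under quantile normalization). SDHB (159 ± 8.71 against 106 ± 1.93) and CYCS (106 ± 4.56 against 77.7 ± 1.92) rose most. Under median-of-ratios scaling 18 of these rose, and under quantile normalization 8 rose and 1 fell. Glycolysis was not called (8 rose and 6 fell of 24, median 0.02, adjusted p = 0.3), and under median-of-ratios scaling 13 rose and 5 fell (median 0.14). PFKFB4 (53.6 ± 2.5 against 12.8 ± 2.26) and PFKFB3 (115 ± 2.12 against 32.3 ± 0.755), which make the activator of phosphofructokinase, rose.

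Ribosomal protein genes fell in 18 of 28 with none higher (median -0.20, adjusted p = 0.00062, or adjusted p = 0.2 with an estimated correlation). Under median-of-ratios scaling only 8 fell and 1 rose, and under quantile normalization 15 fell and 1 rose. RPL10 was at 1230 ± 193 against 2002 ± 96.5 (-0.71). RPL8 was at 1254 ± 235 against 1717 ± 19.5 (adjusted p = 0.0189), a call lost under quantile normalization (0.074), without DMSO replicate 1 (0.054) or 3 (0.051) and with no filter on low values (0.1). Genes of ribosome biogenesis were not called (6 rose and 9 fell of 24, 10 and 6 under median-of-ratios scaling, adjusted p = 0.92), with a median of 0.06, a mean of -0.03 and a test direction of higher. FBL (104 ± 3.32 against 184 ± 6.7) and TCOF1 (22.8 ± 1.37 against 33.5 ± 0.875) fell. The unfolded protein response was not called (7 rose and 8 fell of 21, 9 and 6 under median-of-ratios scaling, median 0.01, adjusted p = 0.74). CHAC1 (158 ± 60.8 against 35.8 ± 4.87) and ATF3 (7.84 ± 0.286 against 2.42 ± 0.262) rose. Lysosomal genes were not called (5 rose and 8 fell of 23, 5 and 9 adjusted over the list alone, 8 and 5 under median-of-ratios scaling, median -0.13, adjusted p = 0.85). GUSB fell (17.5 ± 1.12 against 44.2 ± 3.22). LIPA was at 61.8 ± 2.47 against 130 ± 55.3 (-0.95, adjusted p = 0.0437), a call lost under median-of-ratios scaling (adjusted p = 0.07), with no filter on low values (0.18), with no variance trend (0.072) and on leaving out any library but DMSO replicate 2 (0.087 to 0.13). Without DMSO replicate 2 its log2 fold change was -1.38 (adjusted p = 2.5e-05).

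Only 11 of the 25 listed replication-dependent histone genes reached a mean of 1 TPM. Of these 11, 7 rose and 1 fell (median 1.00, adjusted p = 0.012, or adjusted p = 0.19 with an estimated correlation and 0.23 with no filter on low values). Below 1 TPM, and chosen after their values were seen, HIST1H3B (0.16 ± 0.141 against 1.33 ± 1.08) and HIST1H1B (0.069 ± 0.12 against 0.702 ± 0.343) were lower. Others, such as HIST1H4C (0.694 ± 0.563 against 0.659 ± 0.394), differed little. The call covers the tested members only. HIST1H4H was at 37.2 ± 8.75 against 5.67 ± 1.07 (2.50) and HIST1H2AI at 4.91 ± 1.59 against 0.898 ± 0.457 (1.63). Of 31 histone genes tested in all, 9 have a near-identical copy between which reads can be split, at 95% identity over 80% of the longest transcript. HIST1H4H and HIST1H2AI have none by that criterion. A shorter shared stretch would not meet it, so shared reads are not excluded for these 2 genes. Targets of the oestrogen receptor were not called (5 rose and 5 fell of 11, adjusted p = 0.98), with a median of -0.18, a mean of -0.39 and a test direction of higher. Of the 5 that rose, 1 is ESR1 itself, part of which lies in the fusion. The list includes CXCL12 and PDZK1, the latter at 4.17 ± 0.543 against 1.12 ± 0.271 (1.29).

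**Figure D3:**
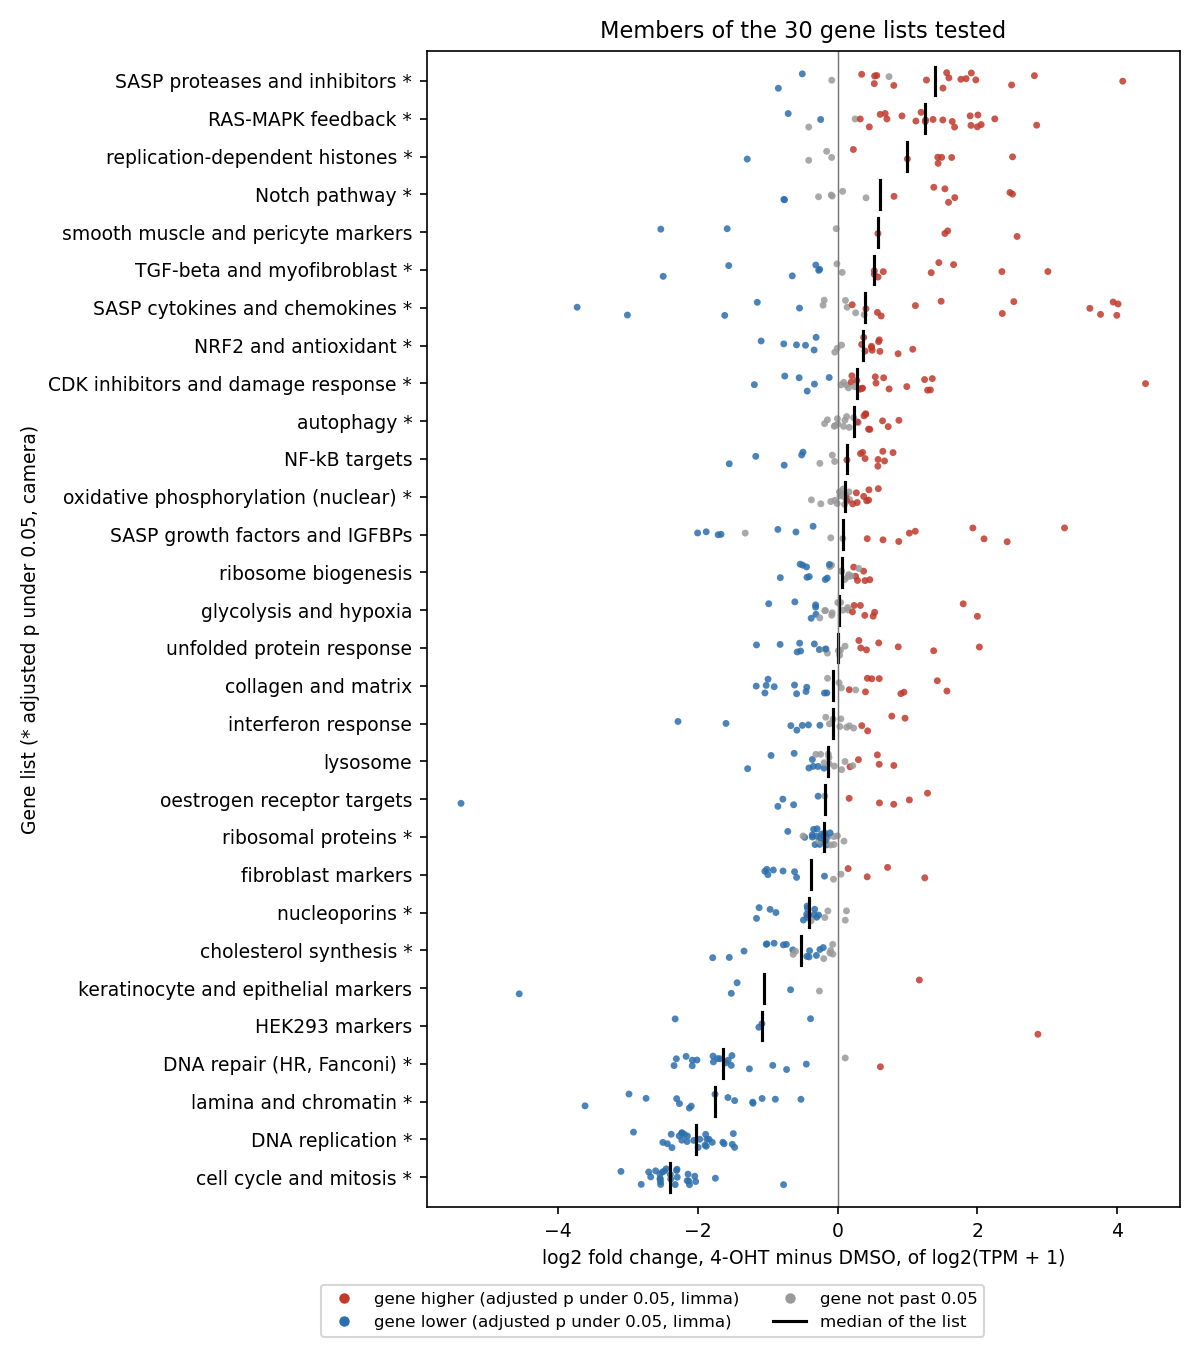
Log2 fold change (4-OHT minus DMSO, of log2(TPM + 1)) of the tested members of each gene list, a point per gene, with a bar at the median of the list and a star where the list was called. All 27 cell cycle genes and all 26 DNA replication genes lie below 0.

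Markers of other cell types were measured in the same way. Fibroblast markers were not called (4 rose and 8 fell of 14, median -0.39, adjusted p = 0.17). DPT rose (3.18 ± 0.32 against 0.759 ± 0.111) and the proteoglycan DCN fell (90 ± 9.49 against 186 ± 12.8). Smooth muscle and pericyte markers were not called (4 rose and 2 fell of 7, median 0.58, adjusted p = 0.17) by the test against other genes except without DMSO replicate 2 (adjusted p = 0.046; up to 0.56 in the other settings). RGS5 rose (24.6 ± 3.99 against 3.30 ± 0.514) and ACTG2 fell (8.79 ± 0.401 against 55.5 ± 0.616). Keratinocyte and epithelial markers fell in 4 of 6 and rose in 1 (median -1.06, adjusted p = 0.074), and the list passed the test under median-of-ratios scaling (0.039) and quantile normalization (0.044), against up to 0.23 in other settings. Besides KRT19, KRT8 fell most, at 11 ± 0.731 against 33.4 ± 2.4 (-1.52). Neural and embryonic kidney genes expressed in HEK293 cells fell in 4 of 5 and rose in 1 (median -1.08, adjusted p = 0.16). NEFM was at 8.42 ± 0.382 against 0.30 ± 0.184 and STMN2 at 0.623 ± 0.309 against 7.05 ± 0.639. By fry, which asks only whether members move on balance in a direction, smooth muscle and pericyte markers were higher (adjusted p = 0.031), and those of fibroblasts (1.9e-05), of keratinocytes and epithelia (4.1e-07) and of HEK293 cells (0.00031) lower. Since fry called all 30 lists tested, these calls do not set the markers apart from other genes. Too few markers were tested for a list result of endothelial cells (2, of which 1 fell), immune cells (3, of which 1 rose) and melanocytes (3, of which 2 fell).

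The 4-OHT libraries had fewer genes at 1 TPM or more (14877 ± 48.3 against 15528 ± 27.2). Ribosomal protein genes took up 8.54 ± 0.0806% of the TPM against 9.86 ± 0.0579%, and the 20 most abundant genes 15.7 ± 0.27% against 14.4 ± 0.182%. Nuclear copies of mitochondrial genes took up 8.36 ± 0.458% against 6.64 ± 0.117% (exact permutation p = 0.1 for each of these 4 measures, 2-sided, the smallest that 3 against 3 allows). The most abundant of these copies (23927 and 18451 TPM on average) are among the 20 most abundant genes, so those shares overlap and are not separate results. Another nuclear copy, MTND4LP30, chosen after its values were seen, had the largest log2 fold change of all (7.21, adjusted p = 0.036). It was read at 3039, 3.87 and 1453 TPM in 4-OHT and 0, 5.68 and 0 in DMSO, so its groups overlapped. The mitochondrially encoded genes were listed at 0 in every library.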

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

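The settings that rescaled TPM without nuclear copies of mitochondrial genes and that kept protein-coding genes only were chosen after the data were seen. Requiring a log2 fold change of at least 1 left 644 genes higher and 1254 lower, fewer by its own construction. In the other settings both counts stayed within 1.5 times 3018 and 4561, from 2166 and 3178 at adjusted p under 0.01 to 4040 and 3579 under median-of-ratios scaling. The rescaling without nuclear mitochondrial copies gave 3202 and 4361, and protein-coding genes alone 2939 and 3877. Leaving out a library at a time gave 2620 to 2755 genes higher and 3903 to 4180 lower, 10 lists higher and 7 lower each time, and a log2 fold change of HRAS of 0.43 to 0.49. With replicate number as a replicate block, 2819 genes were higher and 4246 lower, and libraries of the same number shared little of the spread (correlations of residuals of 0.047, 0.0055 and 0.0066). With an estimated correlation the lists higher fell to 4 and those lower to 5. For autophagy (-0.02), Notch (-0.05) and NRF2 (0.0095) the estimate lay below the preset 0.01, so a larger correlation cannot account for their lost calls. The cell cycle list also had an estimate below the preset (-0.013), and its adjusted p went from 5.1e-17 to 0.012. The weaker values under this setting therefore cannot be read as correlation between genes alone. The other lists that lost the call had estimates from 0.012 to 0.13, and no other cause was tested. By fry, which asks only whether members move on balance in a direction, 15 lists were higher and 15 lower. These are all 30 lists tested, so a call by fry does not set a list apart. Under fry collagen and matrix (adjusted p = 0.014), oestrogen receptor targets (0.00063) and ribosome biogenesis (0.0052) turned from higher to lower, and none of them was called by camera. Camera compares a list with other genes, and the median of all tested genes was -0.094, whereas fry compares with 0. The means of collagen and matrix (-0.02) and of ribosome biogenesis (-0.03) lie between these, where the directions can differ. That of oestrogen receptor targets (-0.39), a mean that includes CXCL12 at -5.39, lies below both, and the cause there was not tested. Over named genes and settings, 1567 values kept direction and call, 17 lost the call, 3 gained it and 0 turned. Over lists and settings the numbers were 537, 15, 13 and 3. Since TPM holds no counts, what depth limits could not be computed.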

Other observations

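Apart from TDO2, ALDH1A1, SFRP1 and CSF2, the genes given here and in the next paragraph were chosen after their values were seen, as were the tests of the fusion transcript and of oestrogen receptor targets, the stricter search for histone copies and the spread of the histone difference. No list of retinoic acid or Wnt genes was tested. CRABP2, which carries retinoic acid in the cell, fell from 556 ± 17.2 to 51.4 ± 6.14 TPM (-3.42), and RARG fell from 64.6 ± 3.54 to 38.4 ± 2.27 (-0.74). STRA6, the receptor for retinol-binding protein, was at 80.8 ± 2.7 against 26.7 ± 3.47 (1.57), and RARB, itself a target of retinoic acid, at 19.7 ± 1.07 against 6.60 ± 0.854 (1.45). ALDH1A3 was higher (12.1 ± 3.02 against 5.89 ± 0.229), though far below the loss of ALDH1A1 in TPM. TDO2 opens the path to kynurenine, a ligand of the receptor AHR, and AHR was at 44.1 ± 3.88 against 21.1 ± 0.985 (1.03), whereas its target CYP1B1 was at 1.09 ± 0.279 against 6.01 ± 0.377 (-1.75).

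The Wnt ligand WNT5A was at 513 ± 12.5 against 198 ± 9.25 TPM (1.37) and the ligand WNT7B at 20.1 ± 0.869 against 0.713 ± 0.203 (3.63), while the antagonist DKK1 was at 40.0 ± 11.9 against 359 ± 83.8 (-3.15), in the same direction as SFRP1. The macrophage growth factor CSF1 fell from 76.9 ± 1.03 to 8.71 ± 0.898 (-3.01), opposite to CSF2. INHBA, which encodes a subunit of activin, was at 174 ± 3.14 against 10.5 ± 1.92. Among abundant transcripts, FKBP1A was at 3877 ± 70.2 against 746 ± 3.15 (2.38, adjusted p = 2.79e-08), TNFRSF21 at 747 ± 6.8 against 79.0 ± 0.287, and TMSB4X at 2127 ± 81.4 against 5889 ± 17 (-1.47).

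Of the 10 splits of the 6 libraries into 3 and 3, 1 called as many genes as the real grouping, the real grouping itself. It called 7579 genes in limma and the highest of the others 0, and 10 splits are too few for a share under 0.05. Every other split has libraries of both groups on each side. The difference between the groups then widens the spread, so the 0 calls say little.

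In the histone list 7 of 11 genes rose while all 26 DNA replication genes fell, though the histone call was lost with an estimated correlation (adjusted p = 0.19) and with no filter on low values (0.23). Over all 31 tested genes of the histone clusters the median was 1.01 (20 higher, 1 lower). A bias of TPM for short transcripts was argued against by 320 other protein-coding genes with no transcript over 1000 nt, whose median was -0.09 (quartiles -0.43 and 0.21). Reads shared between near-identical copies were argued against by the 22 histone genes without such a copy, whose median was 1.32 with 18 higher (1.18 and 16 of 20 under a stricter criterion of 100 nt at 95% identity), while the 9 with a copy had a median of -0.24 with 2 higher. Longer polyadenylated histone transcripts, which are known from cells that have left the cycle, may contribute, but this cannot be told apart: the 14 genes with an annotated transcript over 1000 nt had a median of 1.03 and the 17 others 0.75, a difference of 0.28 with a bootstrap SD of 0.6 (permutation p = 0.55).

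The 37 mitochondrially encoded genes were listed at 0 in all libraries, while 407 nuclear copies of them held 74915 TPM on average. A candidate explanation is that reads of mitochondrial transcripts were assigned to nuclear copies. The 13 copies at least 95% identical to a mitochondrial transcript (3.19% of the copies) held 87.2% of that TPM. This is far above their share of the copies but short of the 90% set beforehand, so the test does not decide. The most abundant copy below 95% was MTCYBP18, at 92.4% identity and 5745 TPM on average. Transcription of the copies themselves was not tested, and by itself it would not put the 37 mitochondrially encoded genes at 0. No biological explanation was tested, and the higher share of these copies in 4-OHT says nothing certain about mitochondrial transcripts.

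HRAS and ESR1, which are joined in the fusion, were both higher in 4-OHT. Scaling between libraries was argued against as the cause, since the log2 fold change of HRAS was 0.57 (SE 0.043) under median-of-ratios scaling. A common source in the fusion transcript would give similar changes, and that of ESR1 exceeded that of HRAS by 0.146 (SE 0.052). This lies past the bound of 2 SE, but the bound ignored that both genes also count the cells' own transcripts, in unknown shares, so a common source cannot be told apart from separate changes. Whether 4-OHT may also have acted on oestrogen receptor targets stays open as well: the list was not called (adjusted p = 0.98), but 5 of its members rose, ESR1 itself among them, and 5 fell, and cells without the fusion were not part of the comparison.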
